A study of Homo sapiens with 2 samples.

How the data were processed

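Alveolar macrophages from the bronchoalveolar lavage fluid of people with asthma were profiled by RNA sequencing before an allergen challenge and 48 h after it, with 1 library at each time. Per the labels' protocols, the cells were purified on a Percoll density gradient and by adhesion, and total RNA was treated with DNase and depleted of ribosomal RNA. Per the same protocols, strand-specific libraries were then made with a directional kit. Whether a library came from 1 donor or from several pooled donors is not given in the sources used here. The reads were aligned with TopHat and compared with Cuffdiff on the GRCh37 (hg19) human genome, per the submitters' processing notes. The versions of both tools and the strand setting used in counting are not given in the sources used here.

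The deposited comparison table holds FPKM (fragments per kilobase of transcript, scaled to the sequencing depth) for each library, computed by the authors with Cuffdiff, per the file headers. It also holds the p-value and q-value of the authors' comparison of 1 library with 1 library, so no replicate stood behind the spread that their test assumed. A second deposited table holds Cuffdiff's estimated count of fragments per gene, which the authors' run placed on a scale common to both libraries. On that scale 1 fragment was worth 1.10 in the pre-challenge library and 0.907 in the post-challenge library, and the product of these values was 1.00. Dividing by them restored whole fragments for 81.0% and 80.5% of the values under 400 (tolerance 0.02). The deposited estimated counts summed to 50807340 and 42766806, and the restored fragments to 46067153 and 47151793, for the pre- and post-challenge libraries. Library columns were tied to sampling times by the sample names in the file headers, which match the titles of the samples. No other content of the tables ties a column to a time, so every direction given rests on those names.

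The tables held 44599 entries, joined by gene identifier because 43 entries stood in a different order in the comparison table. Left out were 4 entries with repeated identifiers, 37 entries whose estimate Cuffdiff marked as failed, and 253 entries on chromosome Y or of X-inactivation transcripts, which are not reported. This left 44305 entries. Of all entries, 28 carried date-like names from spreadsheet conversion. Entries with a mean FPKM of at least 1 over both libraries numbered 12790, among them 1091 unnamed lincRNA transcript models, 355 small RNAs and 6 entries that join several genes. Gene coordinates are those of the deposited tables on GRCh37, rewritten to count from 1, since 1699 deposited loci matched the RefSeq gene length when the start was read as counting from 0 and 232 when read as counting from 1. A deposited locus can take in neighbouring genes.

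For each gene the difference was log2(FPKM + 1) after challenge minus log2(FPKM + 1) before it, which understates the change of low genes. A gene counted as higher or lower when this difference was at least 1 in size (2-fold). With 1 library per time no test between conditions was possible, and no p-value was computed. Folds were computed from the estimated counts on the common scale. Their 95% intervals are exact conditional binomial intervals on the restored, rounded fragments. They cover counting error between these libraries only, not variation between people or repeated libraries, and PCR copies are not independent molecules. Against 0 fragments a floor of 3 fragments per library was used and the fold is given as a lower bound.

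The 32 gene lists were fixed in advance. They covered alveolar macrophage identity, markers of monocytes, eosinophils, neutrophils, T and NK cells, B and plasma cells, mast cells and basophils, dendritic cells, epithelium and erythroid cells, and genes of IL-4 and IL-13 responses, NF-kB and inflammatory cytokines, interferon responses, MHC class II presentation, cholesterol synthesis, lipid handling, cell cycle, immediate early responses, heat shock, glucocorticoid responses, metallothioneins, the clock, matrix remodelling, complement, eicosanoids, oxidative stress, the unfolded protein response, hypoxia and glycolysis, lysosome and phagocytosis, histones, cytokine and growth factor receptors, and ribosomal proteins. For each list with at least 5 measured members, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1), and called outside their range when it lay beyond the central 95%. The percentile describes these libraries and is not a test of the conditions. Intervals of list medians over members are exact 95% order-statistic intervals. MCEMP1 and PTGDR2 were matched under older or newer symbols through gene name tables, and MUC5AC and CSF2RA were not used. Named genes were first drawn without joined entries and without small RNAs, as recognised by symbol. They were the 12 with the greatest positive and the 12 with the greatest negative difference, given at least 50 fragments in the larger library. To these were added up to 4 members past the 2-fold rule from each list, or the 2 with the highest mean where none passed, and the 2 highest markers of each other cell type. Other members named beside a list, and genes picked from the authors' calls, were chosen after their values were seen. Genes whose level follows common genotypes were not named, and some genes that the rule picks are not reported here.

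The computation was tested on simulated libraries of the 12790 genes with counting noise only. The genes to be changed were drawn from those with a mean estimated count above 20. Genes set 3-fold higher passed the 2-fold rule in 88.0% of cases and those set 6-fold higher in 100% of cases. For genes set lower, 82.0% passed at 3-fold and 90.0% at 6-fold. Of the 9 missed at 3-fold 2 fell below the filter on mean FPKM, as did all 5 missed at 6-fold. With neither the filter nor the pseudocount all 9 and all 5 passed, and the highest mean FPKM among them was 2.12. Of 12590 unchanged genes 109 passed (0.866%). All 20 lists drawn from the raised genes alone fell outside the random range, which checks only the computation, as did 7 of 200 random lists.

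Alternatives were other pseudocounts, filters and size rules, and rescaling by the median ratio, by total counts, by edgeR's TMM factors and by DESeq2's size factors on the rounded restored fragments. Others left out the 100 most abundant genes, small RNAs, low-data entries or transcript models, kept failed estimates, or removed a trend with GC content and transcript length taken from GENCODE transcript sequences. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.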

Results

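RNA from purified alveolar macrophages of people with asthma was sequenced before an allergen challenge and 48 h after it, in 1 library at each time. The comparison asks which transcripts differ in abundance between macrophage samples taken before and after the airways meet the allergen. The pre-challenge library held 46067153 assigned fragments and the post-challenge library 47151793. Genes at an FPKM of at least 1 numbered 12249 before and 12941 after challenge. The 10 most abundant genes took 8.02% of the fragments before and 5.66% after. Small RNAs took 0.423% and 0.571% of the fragments but 48.8% and 65.2% of the summed FPKM, because their short length inflates the unit. As each time had 1 library, no difference had a replicate check, and intervals cover counting error only.

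In the post-challenge library all 13 measured markers of dendritic cells were at least 2-fold higher, as were 11 of 22 genes that respond to IL-4 or IL-13, of which 1 was lower. At least 2-fold lower were 12 of 14 heat shock genes and 15 of 22 alveolar macrophage identity genes. F13A1, the coagulation factor XIII A chain made by alternatively activated macrophages, stood at an FPKM of 0.522 before and 108 after challenge, which is 207-fold higher (95% interval 166 to 260). CLEC10A, a galactose-binding lectin of dendritic cells and macrophages, was 63.1-fold higher (52.3 to 76.9), at 1.65 and 106. RND3, an atypical small GTPase, was 18.4-fold lower (17.7 to 19.1), at 371 and 20.1. Among the 12790 genes tested, 1199 (9.37%) were at least 2-fold higher and 823 (6.43%) at least 2-fold lower after challenge. At 4-fold or more these numbers were 381 and 128. The counting interval excluded 1 for 1081 of the higher and 779 of the lower genes. The median difference over all tested genes was -0.08 on the log2 scale, with quartiles of -0.41 and 0.30. Higher genes made up 59.3% of all those past the rule, and 75.2% (1811 higher, 597 lower) when values were scaled to total counts, which moved the median of all genes up by 0.23.

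**Figure D1:**
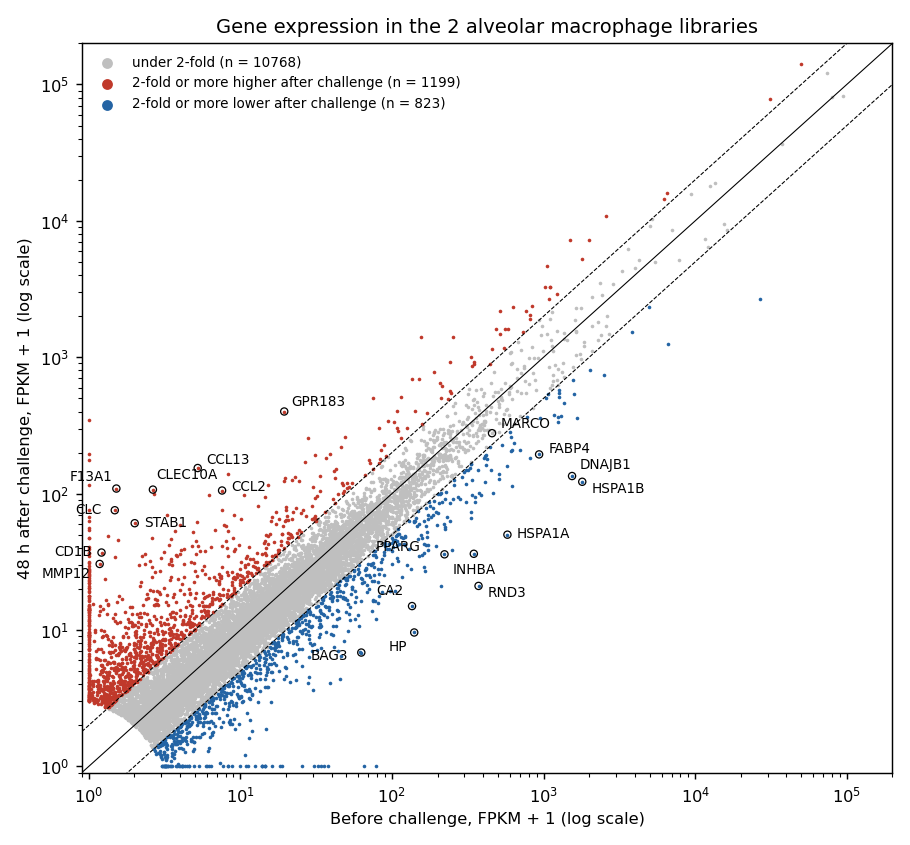
FPKM + 1 of each of the 12790 tested genes before challenge (horizontal, log scale) and 48 h after it (vertical, log scale), 1 library each. Red points are the 1199 genes at least 2-fold higher after challenge on the log2(FPKM + 1) scale, blue points the 823 at least 2-fold lower and grey points the rest, with dashed lines at 2-fold. F13A1 rests at 0.522 before and 108 after, and RND3 at 371 and 20.1.

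The 12 genes with the greatest positive difference were led by F13A1 (chromosome 6, 6144311 to 6320924). CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, was at 0.486 before and 74.6 after. CCL17, a chemokine that attracts T helper 2 cells, was at 1.69 and 97.9, and CCL13, an eosinophil and monocyte attractant on chromosome 17 (32683471 to 32685629), at 4.24 and 153. IGJ, the joining chain of polymeric immunoglobulins, was at 0.348 and 47.7. STAB1, a scavenger receptor gene on chromosome 3 (52529356 to 52569093), was at 1.01 and 59.7. CD1B and CD1C, which present lipid antigens, were at 0.215 and 0.566 before and at 36.0 and 44.6 after. MMP12, the macrophage elastase, was at 0.181 and 29.5, and SPINK1, a trypsin inhibitor, at 0.486 and 33.6. RPL13AP5, a ribosomal pseudogene with 0 fragments before and 564 after, was at least 155-fold higher, but the authors' run marked it as having too little data and its reads can come from RPL13A.

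On the side of the genes lower after challenge, the 70 kDa heat shock genes HSPA1B and HSPA1A went from 1799 to 121 and from 577 to 49.0. Their sequences are near-identical, so the split between them is uncertain. The co-chaperone genes DNAJB1 went from 1540 to 134, DNAJA4 was 10.5-fold lower, and BAG3 went from 61.8 to 5.84. HP, which encodes haptoglobin (chromosome 16, 72088508 to 72094955), stood at 139 and 8.60, a 16.2-fold difference (14.8 to 17.8). INHBA, the activin A subunit, was 9.81-fold lower (9.48 to 10.2), at 346 and 35.2. CA2, carbonic anhydrase II, was at 135 and 14.0. RPPH1, the RNA component of RNase P (chromosome 14, 20811230 to 20811570), was at 26674 and 2673. It is a short RNA that the filter on small RNAs, which went by symbol, did not catch. Its short length inflates its FPKM. The remaining members of the 12 were unnamed transcript models, TCONS_l2_00025701 at least 96.5-fold lower and TCONS_l2_00017557 13.2-fold lower (6.42 to 31.6).

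Of the 22 measured genes known to respond to IL-4 or IL-13, the cytokines of type 2 immunity, 11 were higher after challenge and 1 was lower. The list median was 1.09, above all 10000 matched random lists, and could not change with FCER2, already above it, set to its lower bound. Its 95% interval over members, -0.37 to 3.35, included 0, and the other 10 genes were under 2-fold. Besides F13A1, CCL17, STAB1 and CCL13, ALOX15, the 15-lipoxygenase gene, was at 0.648 before and 15.8 after, which is 24.4-fold higher (19.2 to 31.4). FCER2, the low-affinity IgE receptor, had 0 fragments before and 959 after, at least 263-fold higher. CD209 was at 1.60 and 23.4. The members did not all move alike. CCL24, the eotaxin-2 gene, was at 74.4 before and 15.3 after, CCL18 at 1356 and 712, and the receptor gene IL4R at 28.8 and 22.1. In the same library 47 of the 54 measured markers of dendritic cells, eosinophils, T and NK cells and monocytes were also at least 2-fold higher.

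Markers of several other leukocytes were higher after challenge. All 13 measured dendritic cell markers were higher, with a list median of 2.54. CD1E was at 0.284 and 22.6, CD1A at 0.185 and 12.7, and the transcription factor gene IRF4 at 1.95 and 26.2. Of 8 measured eosinophil markers 6 were higher (median 2.32, 95% interval over members -0.80 to 5.67), and with a mean FPKM of at least 5 too few were left to place the list. The eotaxin receptor gene CCR3 was at 0.0769 and 7.35, IL5RA at 0.110 and 6.05, and PTGDR2, the prostaglandin D2 receptor of T helper 2 cells and eosinophils, at 0.112 and 5.22, while EMR1 was at 26.5 and 14.8. Of 18 measured T and NK cell markers 17 were higher (median 1.62). That median could not change with GZMK, already above it and at 0 fragments before, set to its lower bound. Among the higher T and NK cell markers were GZMB at 0.869 and 13.7, LCK at 1.98 and 9.96, CD247 at 0.553 and 4.65, and GNLY at 0.215 and 4.07. CD2 was at 9.17 and 30.5 and IL7R at 170 and 389. Of 15 measured monocyte markers 11 were higher and 2 lower (median 1.52, interval over members -0.09 to 3.08). FCN1, CD93 and CCR2 were 13.2-fold, 12.2-fold and 11.4-fold higher, whereas LYZ went from 4974 to 2337, THBS1 from 576 to 157, and S100A9 was at 291 and 273. These 4 medians lay above all 10000 matched random lists.

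The other cell type lists held fewer expressed genes. Of 7 measured neutrophil markers 1 was higher and 2 were lower, and the median of -0.20 lay at percentile 20.5 of the random lists. CAMP went from 9.78 to 0.212, VNN2 from 9.29 to 3.74, and PROK2 from 0.347 to 1.91. Of 4 measured B and plasma cell markers 3 were higher, BANK1 at 0.395 and 5.37, MS4A1 at 0.172 and 2.80, and IGJ. Of 4 measured mast cell and basophil markers, FCER1A, the high-affinity IgE receptor alpha chain that dendritic cells also carry, was at 1.62 and 46.1, CPA3 at 0.204 and 4.01, HDC at 0.0669 and 3.05, and ENPP3 at 3.42 and 1.15. Of 4 measured epithelial markers SLPI was higher (0.764 and 2.61), with KRT18 at 3.37 and 1.84 and KRT8 at 1.59 and 2.14. The erythroid list had 1 measured member, HBB at 2.64 and 4.56, and HBA2 was at 0.173 and 0.427.

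Genes of alveolar macrophage identity were lower after challenge. Of 22 measured members 15 were lower and 0 higher, and the median of -1.74 lay below all 10000 matched random lists. PPARG, the nuclear receptor that drives alveolar macrophage differentiation (chromosome 3, 12329349 to 12475855), was 6.33-fold lower (6.09 to 6.59), at 221 and 34.9. FABP4, a fatty acid carrier and PPARG target, was 4.84-fold lower (4.71 to 4.97), at 934 and 193, and PCOLCE2 went from 96.3 to 18.4. The members under 2-fold included MARCO at 456 and 277, MRC1 at 92.0 and 85.5, and CD163 at 305 and 447. Markers of dendritic cells, eosinophils, T and NK cells and monocytes stood higher in the same library, as given above.

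Cholesterol synthesis genes were also lower, 12 of 19 measured with 0 higher, and the median of -1.24 lay below all 10000 random lists. The methylsterol monooxygenase gene MSMO1 was 5.60-fold lower (5.33 to 5.88), at 103 and 18.5. CYP51A1, a sterol demethylase gene, was at 68.0 and 20.3. In the same library 47 of the 54 measured markers of dendritic cells, eosinophils, T and NK cells and monocytes were at least 2-fold higher. Of 16 measured lipid handling and efflux genes 3 were higher and 4 lower. PLTP, the phospholipid transfer protein gene, was 6.71-fold higher (6.24 to 7.23), and the efflux pump gene ABCA1 at 30.3 and 91.8. LPL went from 353 to 85.7, SCD from 701 to 208 and PLIN2 from 448 to 147. The median of -0.30 lay at percentile 15.8.

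Complement genes were lower in 6 of 16 measured members with 0 higher, and the median of -0.74 lay at percentile 0.01 (interval over members -1.42 to 0.07). Beside them stood the 47 of 54 markers of dendritic cells, eosinophils, T and NK cells and monocytes that were higher in this library. The C1 inhibitor gene SERPING1 was 4.83-fold lower (4.66 to 5.02), at 195 and 40.5. C1QA and C1QB, chains of the recognition protein of the classical pathway, went from 1659 to 358 and from 633 to 236, and CFD from 19.4 to 5.53. The 15 measured eicosanoid genes went both ways, 4 higher and 6 lower, with a median of -0.27 (percentile 17.6) and a mean of 0.13. PLA2G7, the platelet-activating factor acetylhydrolase gene, was 18.4-fold higher (16.5 to 20.5), at 5.23 and 97.2, and the prostaglandin E2 receptor gene PTGER2 was at 2.47 and 23.6. The lower members included the 5-lipoxygenase gene ALOX5 at 613 and 258, ALOX5AP at 621 and 207, LTA4H, the leukotriene A4 hydrolase gene, at 1563 and 677, and HPGD, which inactivates prostaglandins, at 51.9 and 10.9.

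Heat shock genes had the lowest list median. Of 14 measured members 12 were lower and 0 higher, and the median of -1.87 lay below all 10000 matched random lists. Higher in that library were 47 of the 54 measured markers of dendritic cells, eosinophils, T and NK cells and monocytes. Beyond HSPA1A, HSPA1B, DNAJB1 and BAG3, the 90 kDa chaperone gene HSP90AA1 went from 2496 to 736 and HSPH1 from 620 to 113. HSPA5, the chaperone of the endoplasmic reticulum, was at 185 and 268. Immediate early genes were lower in 7 of 24 measured members and higher in 1, IER3, and the median of -0.66 lay at percentile 0.02 (interval over members -1.01 to 0.11). JUN went from 809 to 183, EGR2 from 173 to 41.2, NR4A1 from 242 to 62.3 and ATF3 from 409 to 120. Of 13 unfolded protein response genes 1 was higher and 2 were lower (median -0.02, percentile 70.6). These were ASNS at 1.29 and 4.33, DDIT3 at 247 and 37.4, and ATF3.

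Inflammatory genes differed within their own list. Of 29 measured NF-kB and inflammatory cytokine genes 14 were higher and 4 lower, and the median of 0.98 lay above all 10000 random lists. CCL2, a monocyte chemoattractant, was 15.9-fold higher (13.5 to 18.8), at 6.58 and 104. IL10 was at 1.19 and 19.9, the NF-kB target gene BIRC3 at 7.07 and 56.9, CCL7 at 0.155 and 6.26, and IL6 at 8.28 and 38.5. The lower members were TNF at 169 and 46.8, CXCL5 at 251 and 90.5, CXCL3 at 121 and 48.3, and IL1A at 106 and 43.8. Interferon response genes were lower in 8 of 30 measured members and higher in 2, with a median of -0.56 below all 10000 random lists. OASL went from 162 to 35.8, IFI27 from 149 to 34.0 and OAS1 from 46.5 to 16.5, while ISG20 went from 1.67 to 7.80. As above, dendritic cell, eosinophil, lymphocyte and monocyte markers stood higher in the library in which these NF-kB genes were higher and these interferon response genes lower.

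Of 14 cytokine and growth factor receptor genes 4 were higher and 0 lower (median 0.48, percentile 99.9). Among them were CXCR4 at 45.2 and 217, IL2RA at 0.565 and 4.61, and CXCR3 at 0.820 and 3.80. Lymphocytes also carry these receptors, and in the same library 17 of the 18 measured T and NK cell markers were higher (median 1.62). None of the 13 MHC class II presentation genes passed the 2-fold rule (median -0.17, percentile 43.8). HLA-DRA was at 11608 and 7343, and HLA-DPA1 at 2298 and 1813. Of 26 lysosome and phagocytosis genes 4 were higher and 3 lower (median 0.02, percentile 88.4). The inhibitory IgG receptor gene FCGR2B was at 2.27 and 68.4, although reads shared with FCGR2C leave its level uncertain. MERTK, which takes up apoptotic cells, was 28.3-fold higher (22.9 to 35.4), at 0.592 and 16.8, and TLR2 was at 22.1 and 77.3. Of 16 matrix and remodelling genes 5 were higher and 3 lower (median 0.19, interval over members -0.44 to 1.59, percentile 97.8), and the list lay inside the random range with a mean FPKM of at least 5 or at least 0.1, with no filter on low values, and against random lists not matched on expression. MMP9 was 52.3-fold higher (34.7 to 82.8), at 0.251 and 13.2, and the osteopontin gene SPP1 was at 3.28 and 38.2, whereas SPARC went from 125 to 29.2 and the fibronectin gene FN1 from 1366 to 462.

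The remaining lists had few members past the rule. Of 24 cell cycle genes 1 was higher, RRM2 at 5.08 and 11.8 (median 0.24, percentile 98.7), and the list lay inside the random range with a mean FPKM of at least 5 and when the mean of the members replaced the median. Histone genes, whose copies share reads, had 3 of 14 higher, HIST1H3A, HIST1H1C and HIST1H4A (median 0.18, interval over members -0.35 to 1.01, percentile 98.1), and that list lay inside the random range under the count-based scalings, with the GC content and length trend removed, against unmatched random lists, and by the mean of the members. Ribosomal protein genes had 0 of 77 past the rule and a median of 0.14 (percentile 99.97). RPS29 was at 960 and 1467, and RPL41 at 2443 and 2867. Hypoxia and glycolysis genes were higher in 3 of 20 and lower in 1, HK2 (median 0.02, percentile 81.4), with SLC2A1 at 1.82 and 8.86 and VEGFA at 7.79 and 25.4. Glucocorticoid responsive genes had 2 of 13 higher and 3 lower (median 0.08, mean -0.08, percentile 85.3), with the adenosine receptor gene ADORA3 8.67-fold higher, THBD at 465 and 100, IRS2 at 77.4 and 33.1, and ANXA1 at 1264 and 572. Of 15 oxidative stress genes 1 was higher, SLC7A11 at 0.244 and 5.90, and 1 lower, CAT at 129 and 62.3 (median -0.20, percentile 34.5). Of 14 clock genes RORA was higher (3.62 and 11.6) and BHLHE41 lower (79.7 and 27.0), with a median of -0.06 at percentile 54.4. Metallothionein genes, whose copies share reads, had 1 of 9 higher, the zinc exporter gene SLC30A1, and 1 lower, MT1L (median 0.08, percentile 72.7). Of the 28 lists with at least 5 measured members, 11 lay above and 6 below the central 95% of random lists.

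**Figure D2:**
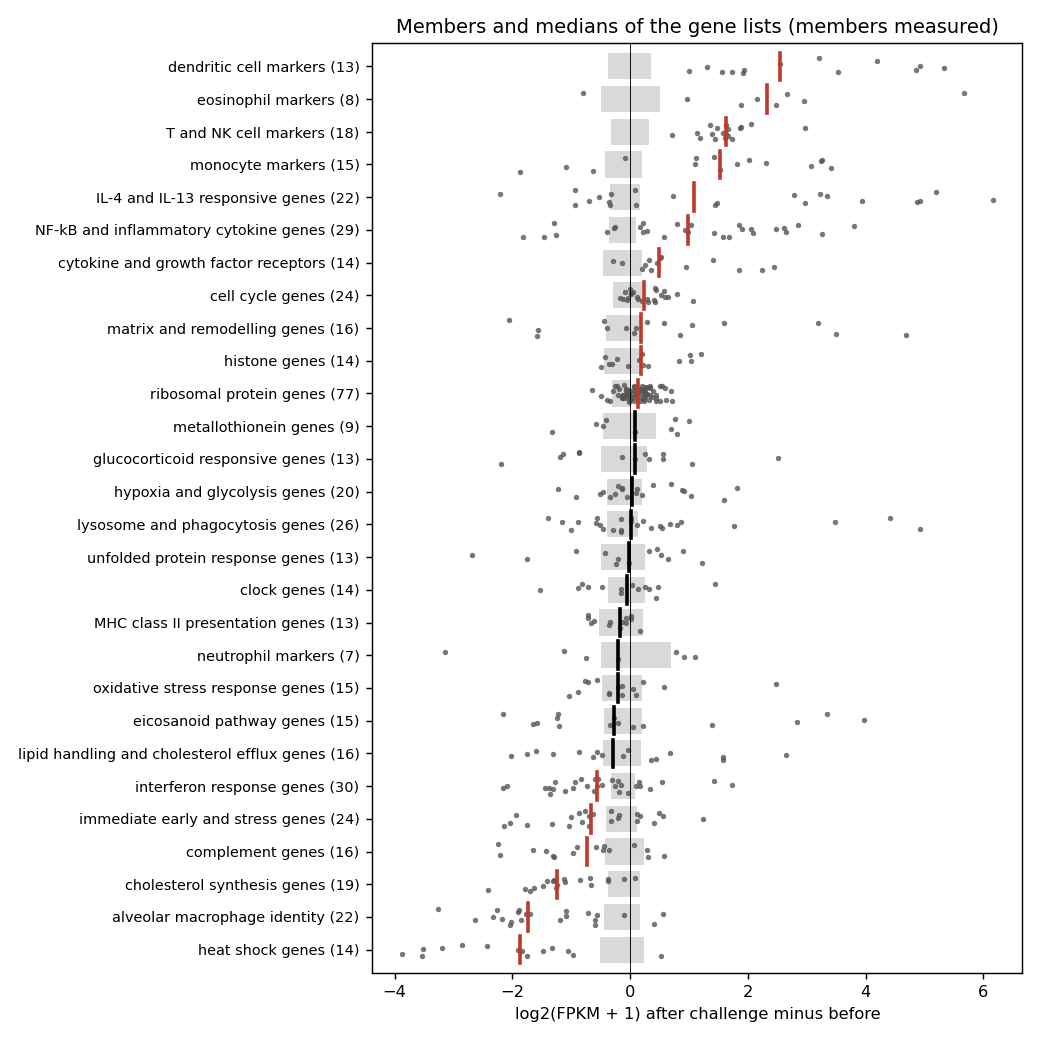
Difference in log2(FPKM + 1), after challenge minus before, for the members of the 28 lists with at least 5 measured genes, sorted by median. Points are genes, vertical bars list medians (red when outside the central 95% of 10000 matched random lists, whose range is the grey band), and numbers in brackets the members measured. Dendritic cell markers (median 2.54) lie at the top and heat shock genes (median -1.87) at the bottom.

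The authors' deposited table called 83 genes significant, 72 of them higher and 11 lower after challenge. Of these calls of the authors' deposited table, 38 were listed at 0 before challenge and 1 at 0 after. F13A1, CLEC10A, STAB1, CCL13, CD1E, FCGR2B, PLA2G7, CD93, CCR2 and BIRC3 were among the higher calls of the authors' deposited table. So were, in the authors' deposited table, GPR183, a receptor for oxysterols, at 18.5 and 399, and IL1RL1, the IL-33 receptor, listed at 0 and 9.13. The lower calls of the authors' deposited table included RND3, HP, INHBA, CA2, DNAJA4, HSPA1A, BAG3, PPARG and MSMO1. The smallest q-value in the authors' deposited table was 0.0156. With a mean FPKM of at least 1, 51 of the 83 calls of the authors' deposited table remained, 41 higher and 10 lower, and all 51 passed the 2-fold rule. These q-values come from 1 library at each time and describe the pair of libraries, not the conditions.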

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

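The gene lists, the 2-fold rule and most alternatives were chosen before the data were examined. Tests chosen after the values were seen were keeping failed estimates, leaving out low-data entries, leaving out transcript models, and removing the GC content and length trend. No paired analysis was possible because each sampling time had 1 library. Of 54 recounts of genes past the rule, 45 stayed within 1.5 times the original count. With a mean FPKM of at least 5, which tests fewer genes, 1143 passed, 593 of them higher. Scaling to total counts gave 1811 higher genes, and the cause was not tested beyond its shift of the median of all genes by 0.23. Leaving out the 100 most abundant genes shifted the median of all genes by 0.11 and put the higher share at 66.9%. By construction, a difference of at least 2 (log2) left 509 genes (381 higher, 128 lower), and one of 1.5-fold gave 4128 (2025 higher, 2103 lower). Of the genes in the authors' deposited table, 0 had a q-value under 0.01, and 51 of the 83 calls had a mean FPKM of at least 1. The smallest q-value, 0.0156, was shared by calls as different as F13A1 (207-fold) and INHBA (9.81-fold). The limit of 0.01 could therefore not separate the calls. Of 474 recomputed list medians, 465 stayed within the 95% interval of the original median over members, and 0 of the lists outside the random range changed sign. Lists outside the random range numbered 15 to 18 against 17 originally. Those lost in at least 1 alternative were histone, matrix, cell cycle and eosinophil lists, the eosinophil list only with a mean FPKM of at least 5. Those gained were B and plasma cell, mast cell and basophil, metallothionein and lysosome lists. Of 1740 values of named genes, 410 moved beyond the counting interval and 0 of those past the 2-fold rule changed sign. The trend with GC content and length explained 6.57% of the variance over the 11361 genes with values (88.8%). Depth limits the low genes: a gene with 0 fragments in a library can stand at up to 3 fragments there, and differences under that floor were not detectable.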

Other observations

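The families in the next paragraphs and their limits on members were picked after their values were seen, as were the measure of what a correction takes from each member, the tests on the dendritic cell markers alone, and those of scaling, of leukocyte share, of handling stress, of macrophage share and of macrophage replacement. The other 3 tests of GC content and transcript length were set out before their results were seen.

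Beside all families given here stand 47 of 54 measured markers of dendritic cells, eosinophils, T and NK cells and monocytes. These were at least 2-fold higher in this library, against 1 of 7 neutrophil markers. Of 13 measured CC chemokine genes 6 were higher and 1 lower, with a median of 0.93. Over the 12 members measured under every scaling it was 1.27 to 1.69 under the 5 other scalings. CCL8, a monocyte attractant, was at 1.73 before and 14.3 after, and CCL22 at 0.421 and 2.93. Of 9 CXC chemokine genes, which mostly attract neutrophils and T cells, 1 was higher and 3 lower, and the median of -0.15 lay at percentile 42.9 of the random lists. It was 0.07 when values were scaled to total counts, which moved the median of all genes up by 0.23. The difference between the CC and CXC families was not tested. CXCL1 was at 8.15 and 37.2 and CXCL16 at 177 and 80.5. Among 9 ADAM genes, most of which encode membrane proteases, 3 were higher and 1 lower (median 0.54, and 0.55 to 0.79 over the same members under the other scalings). ADAM8 was at 1.53 and 30.8, ADAM19 at 3.79 and 40.2, and ADAM17, the TNF-releasing protease, at 138 and 61.8. Of 9 Toll-like receptor genes 2 were higher, TLR2 and TLR10, and 0 lower.

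In the 13 semaphorin and plexin genes 3 were higher, among them PLXNC1 at 2.98 and 58.0 and its ligand SEMA7A at 1.27 and 14.2. Of 6 MS4A genes 3 were higher and 2 lower, and MS4A6A was at 114 and 508 while MS4A7 was at 422 and 178. Of 24 ABC transporter genes 6 were higher and 2 lower, with ABCA6 at 0.348 and 7.53 and ABCG1 at 212 and 85.2. The annexin gene ANXA6 was at 14.3 and 115, against ANXA5 at 1130 and 626. Of 15 integrin genes 0 were higher and 4 lower, with a median of -0.31 at percentile 8.46 of the random lists. Over the same 15 members it was -0.34 to -0.07 under the other scalings, and over the 20 members that the count-based scalings measured it was up to 0.24. The lower genes included ITGB8 at 33.1 and 9.77 and ITGAE at 19.3 and 5.83. Box C/D small nucleolar RNA genes were higher in 67 of 136 members and lower in 15 (median 0.99). Rounded to 0 fragments in 1 library were 21 of them, of which 3 had more than 3 fragments in the other, and with these 3 at their bound the median was 0.98. Among the 69 members with at least 20 fragments in the larger library 43 were higher and 1 lower (median 1.24). The median was 1.08 with FPKM rescaled by the median ratio, 0.82 over the 98 members left without the 100 most abundant genes, and 0.78 to 0.94 over the 37 or 38 members that the count-based scalings measured. Box H/ACA genes were higher in 29 of 89 and lower in 5 (median 0.68). Of the 9 at 0 fragments in 1 library 3 had more than 3 in the other, and with these at their bound the median was 0.67. Among the 59 with at least 20 fragments in the larger library 14 were higher and 2 lower (median 0.68), and over the 25 members measured under every scaling the median was 0.52 to 0.80 under the other scalings. The FPKM of such short RNAs depends strongly on the length range of the sequenced fragments.

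All 13 measured dendritic cell markers and 11 of 22 IL-4 and IL-13 responsive genes were at least 2-fold higher. The dendritic cell median was 2.62 with the GC content and length trend removed and at least 2.63 under 5 other scalings, and the IL-4 and IL-13 median 1.12 and at least 1.16, above the central 95% of random lists each time. The dendritic cell interval over members also lay above that range each time. The IL-4 and IL-13 interval overlapped it each time, and was -0.39 to 3.40 with the trend removed. Removing the trend took at most 0.01 (log2) from the typical member of either list (upper bound of the 95% interval over members). With the trend removed, 12 of the 13 dendritic cell markers and all 11 IL-4 and IL-13 genes stayed at least 2-fold higher, which argues against the trend as the cause. The scalings took at most 0.02, and all 13 and all 11 genes stayed. Each scaling moves all genes together, random lists included. A list's place among random lists could therefore hardly change, and is no test of the authors' scaling. A larger share of other leukocytes in the later library is a candidate explanation. Of the 54 measured markers of 4 cell types, 87.0% were at least 2-fold higher (34 of 41 without the dendritic cell markers). The 4 types were picked after their values were seen, so a high share partly follows from that choice. Of the 7 measured neutrophil markers, left out of that share, 1 was higher and 2 were lower. After challenge CLC stood at an FPKM of 74.6 and CD3D at 21.3. Other facts limit this explanation. Before challenge 11 markers, 9 of them of monocytes, already stood at an FPKM of at least 10. The gradient and adhesion steps serve to remove granulocytes and lymphocytes. That 0 markers were shared with another list only reflects how the lists were drawn up. A response of the macrophages to the challenge stays open beside a larger leukocyte share, since genes such as F13A1 and STAB1 are made by macrophages too.

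Heat shock genes were lower after challenge. The list median was -1.84 with the GC content and length trend removed. Its interval over members lay below the central 95% of random lists, which argues against that trend as the cause. Under 5 other scalings the median was at most -1.63, also with intervals over members below that range. Each scaling holds a common factor that moves random lists too, so this place among them is no test of the authors' scaling. Stress during lavage or purification of the earlier sample may have raised these genes there, as the immediate early genes, which handling also induces, had a median of -0.66 (interval over members -1.01 to 0.11). With 1 library per time, handling and sampling time cannot be told apart. An effect of the challenge itself was not tested separately.

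Alveolar macrophage identity genes were lower after challenge, with a median of -1.67 after removal of the GC content and length trend. Whether a lower share of macrophages raised every other cell type alike could not be decided. The medians of 5 other cell types lay 2.75 apart on the log2 scale, from dendritic cells (95% interval over members from 1.56 upward) to neutrophils (up to 1.11). The neutrophil interval spans all 7 members, -3.15 to 1.11. The difference in log2(FPKM + 1) understates the change of low genes, so equal folds need not give equal medians. A lower share of macrophages with unequal rises of other cells was not tested. Replacement of resident cells by newly arrived macrophages may contribute, as monocyte markers had a median of 1.52 (interval over members -0.09 to 3.08). Resident cells that changed their expression would give the same values, so these cannot be told apart with 1 library per time.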
